A study of Caenorhabditis elegans with 22 samples.

How the data were processed

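Dam::EMR-1 and GFP::Dam methylation was measured in 22 libraries of L1 larvae in 8 groups, and per the labels the fusions were expressed in the intestine by FLP recombination under the elt-2 promoter. The hsp-16.41 promoter was used without heat shock. RNAi against mrg-1 or a control lasted 66 h at 20 °C in the mothers, and hatched larvae spent 2.5 h in liquid culture with bacteria that lack Dam. One replicate of mrg-1 RNAi alone was removed for technical reasons per the labels.

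The deposited count tables give the count of mapped reads per bin of 1, 10 and 100 kb on build ce11 for each library, with no normalization. The deposited log2 tables give, per background, the log2 of the mean over replicate numbers of the Dam::EMR-1 share of reads divided by the GFP::Dam share. This formula held to within 1e-06 of the deposited counts in the bins that could be compared. These had reads in every GFP::Dam library and in some Dam::EMR-1 library of the background. In wild type 61121 bins of 1 kb were compared and 39154 were not, and at 10 kb 9908 and 122. The deposited log2 values list 26819 wild-type bins of 1 kb as 0. The aligner and its filters are not given in the sources used here, nor is the treatment of reads that map to repeats. Gene names and positions came from an annotation of the same assembly.

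Libraries held 2246130 to 18737200 reads. The median bin held 79 to 518 reads at 10 kb, 0 to 16 at 1 kb and 1551 to 11383 at 100 kb, and 0.598% to 9.95% of 10 kb bins had no read. Tests were run in R 4.3.3 with edgeR 4.0.16 (TMM scaling, quasi-likelihood), limma 3.58.1 and DESeq2 1.42.0. One edgeR fit over all 22 libraries gave each contrast, and of 10030 nuclear 10 kb bins 9960 passed the edgeR filter on low counts. Bins and chromosome parts were called at a Benjamini-Hochberg adjusted p under 0.05. Contrasts of backgrounds compared the Dam::EMR-1 to GFP::Dam ratio between groups. The SE of a fold change is its absolute log2 divided by the square root of the quasi-likelihood F statistic.

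Pair values per chromosome part are means over 10 kb bins of the log2 ratio of CPM with a pseudocount of 1 between a Dam::EMR-1 library and the GFP::Dam library of the same number. Arms are the outer parts and the centre the inner part of each chromosome divided into 3 equal lengths. Differences of pair values were tested by exact two-sided permutation, and the 18 parts by limma over 5 contrasts together. Strains of 1 replicate number were grown in parallel per the labels, so numbers pair the samples. As a check of the numbers, deviations from group means correlated above 0.1 between libraries of the same number in 15 of 15 GFP::Dam comparisons and 12 of 15 Dam::EMR-1 comparisons. Differences within replicate numbers are given for the comparisons of pair values, and the number was also used as a block.

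Design, gene lists, named-gene rule and alternatives were set before the data were examined, except where the text says otherwise. The rule named the 12 called bins with the largest ratio each way in wild type and in each background against wild type, and 3 each way for other contrasts. Every replicate pair had to lie on the same side of the reference, with at most 1 bin per 100 kb. The name came from the protein-coding gene with a standard symbol that overlapped the bin most, however small the overlap. Values given for a named gene are those of its bin. Genes of the targeted loci were always named. Only the wild-type contrast had called bins at 10 kb. The 13 lists were intestine, muscle, neuron, hypodermis, germline, ribosome and proteasome, chemoreceptors, F-box/MATH/BTB, C-type lectins, nuclear hormone receptors, collagens, histones and major sperm proteins, each as its distinct 10 kb bins. They were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. Lists were called by the first of these. The planned test fry, which does not set a list against the other bins, was also run. Histone and major sperm protein genes have near-identical copies, so their read assignment is uncertain.

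The pipeline was tested on simulated data. At 10 kb the test of cec-4 against wild type recovered 0, 0, 10 and 32 of 50 bins changed by log2 1, 2, 3 and 5, with 0 wrong calls. At 100 kb it recovered 14, 48, 50 and 50 of 50, with 6 wrong calls. Alternatives were other bin sizes, DESeq2, scaling by library size, no filter, replicate blocks, a pseudocount of 5, other arm boundaries, counts summed over parts, the deposited log2 table, the contrast's own groups for the spread and leaving out each library or pair. Added after seeing the data were 100 kb bins with blocks or library-size scaling, blocks per fusion, centring on the genome mean, thinning to the shallowest library, leaving out the ribosomal RNA bin, list tests relative to the same chromosome part, permutation within strata, and swaps within the same replicate number. No sequence-based correction for the density of GATC sites was made, since no genome sequence was at hand. Mitochondrial reads were left out of all tests.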

Results

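DNA adenine methylation left by a tethered bacterial methyltransferase (DamID) was sequenced from intestine cells of Caenorhabditis elegans L1 larvae. Dam::EMR-1 carries Dam on emerin, a protein of the inner nuclear membrane, and marks DNA near the nuclear periphery. GFP::Dam diffuses freely in the nucleus and marks accessible DNA. Both fusions were measured in 4 backgrounds: wild type, mrg-1 RNAi, the cec-4 deletion, and mrg-1 RNAi in cec-4 larvae (called the combination). CEC-4 is a chromodomain protein at the nuclear periphery that anchors chromatin with methylated H3K9, and MRG-1 is a chromodomain protein of chromatin. The 22 libraries form 8 groups of 3 replicates, except the 2 groups of mrg-1 RNAi alone, which hold replicates 2 and 3.

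Libraries held 2246130 to 18737200 mapped reads. Dam::EMR-1 libraries of wild type were the shallowest group, at 2246130 to 3090300 reads. The median 10 kb bin held 79 to 518 reads, depending on the library. The library with the most bins without a read was Dam::EMR-1 cec-4 replicate 1, where 9.95% of the 10 kb bins were empty at 8202910 reads. Reads are PCR products without molecular identifiers, so copies of 1 molecule may count as several reads, which the floors do not allow for. SE and SD values reflect the spread between libraries or pairs. Strains were grown in parallel within each replicate number according to the labels, which say no more about separate cultures, so p-values measure the spread between these samples. Values are log2 ratios of Dam::EMR-1 to GFP::Dam unless another quantity is named.

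The first question was whether the targeted loci differed between strains. The cec-4 gene (chromosome IV, 7576181 to 7577325) lay in a 10 kb bin low in Dam::EMR-1 in wild type, with log2 −3.51 ± 0.55 (SE, n = 3 per fusion). Its locus kept its reads in cec-4 strains. Summed over both fusions, the 10 kb bin differed from the other strains by log2 0.30 ± 0.27 (SE), which was not called. The 1 kb bins over the gene averaged 36.9 reads against 21.9 and 106 against 115 in the other strains, before scaling. Their fitted log2 differences were 2.41 ± 0.66 and 0.28 ± 0.42 (SE, adjusted p 0.965 and 1.00, edgeR). The first of these bins held 0 reads in Dam::EMR-1 of wild type. The labels give no breakpoints for the deletion, so these bins do not check the genotype. The mrg-1 gene (chromosome III, 12871029 to 12874656), which RNAi leaves in the genome, had a wild-type log2 of 0.17 ± 0.50 (SE, adjusted p = 0.792, edgeR). The emr-1 gene (chromosome I, 1842445 to 1843222) was lower in Dam::EMR-1, at −1.09 ± 0.41 (SE, adjusted p = 0.0305, edgeR). With scaling by library size alone it stood at −0.93 (adjusted p = 0.0943), and the call held in only 1 of 6 fits that left out a library, the one without GFP::Dam wild type replicate 3. The heat-shock gene hsp-16.41 (chromosome V, 1805178 to 1805875), whose promoter drives the fusions, stood at 1.19 ± 0.56 (SE, adjusted p = 0.0764, edgeR). Without GFP::Dam wild type replicate 1 it was called, at an adjusted p of 0.0455. Against wild type, the ratio of the mrg-1 bin differed by 2.06 ± 0.80 with mrg-1 RNAi, −0.92 ± 0.71 in cec-4 and 0.57 ± 0.71 in the combination (SE). That of the emr-1 bin differed by −1.17 ± 0.64, −1.49 ± 0.57 and −1.09 ± 0.57 in the same order. None of these differences was called.

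In wild type, the comparison of Dam::EMR-1 with GFP::Dam asks which regions lie near the nuclear membrane in intestine. Bins higher in Dam::EMR-1 lay mostly in autosome arms and lower ones mostly in centres and on X, where arms are the outer parts and the centre the inner part of a chromosome divided into 3 equal lengths. In autosome arms 2310 of 5458 tested 10 kb bins (42.3%) were higher and 701 (12.8%) lower. In autosome centres 67 of 2736 bins (2.45%) were higher and 1428 (52.2%) lower. The centre of chromosome II (5090001 to 10190000) stood lowest, with 385 of 509 bins lower and 0 higher. The X chromosome was low in its arms too, where 409 of 1177 bins (34.7%) were lower and 148 (12.6%) higher. In the X centre 346 of 589 bins (58.7%) were lower and 2 higher.

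**Figure D1:**
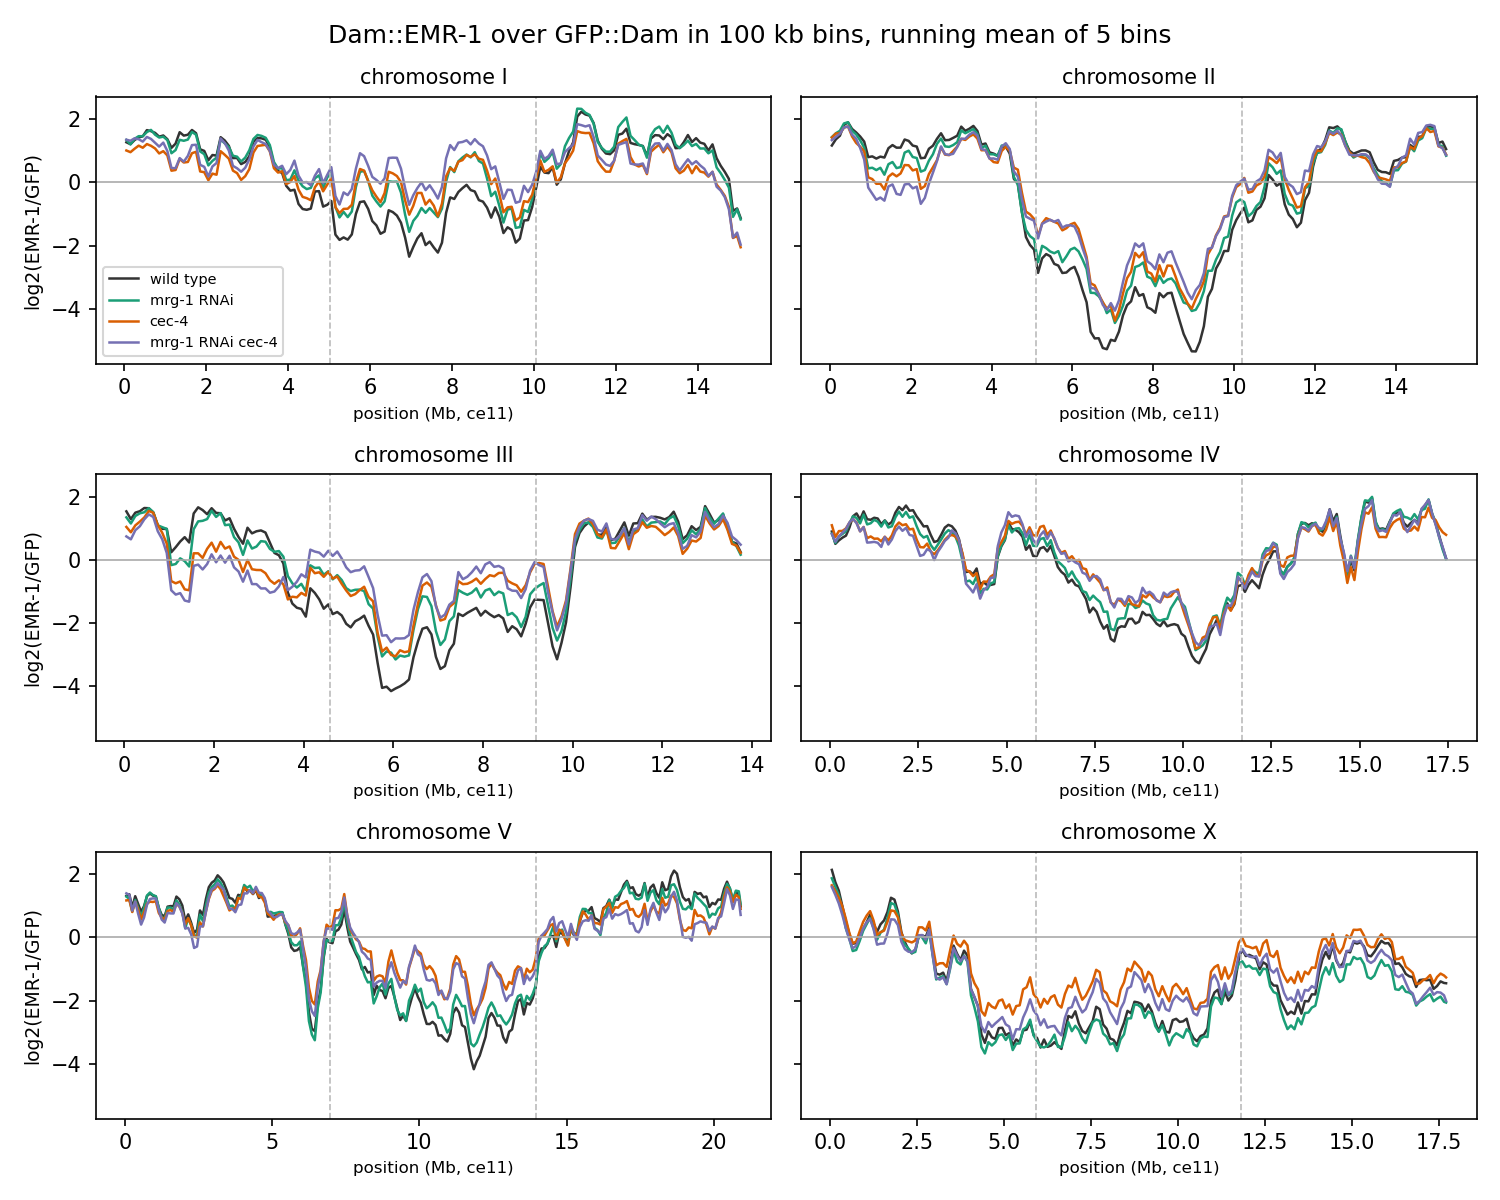
Log2 ratio of Dam::EMR-1 to GFP::Dam (vertical axis) along each of the 6 nuclear chromosomes (horizontal axis, position in Mb), as running means of 5 bins of 100 kb, one line per background; dashed lines divide each chromosome into 3 equal parts. The wild-type mean of the chromosome II centre is −3.26 and its mean in cec-4 is −1.90.

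Values of named genes are those of whole 10 kb bins, which the gene may cover only in part. For example, srv-15 ends at 15910091 and barely reaches into its bin from 15910001. The genes named for the bins with the highest wild-type ratios all lay in arms. They included srz-23, a chemoreceptor gene (chromosome IV, 3453608 to 3454788), at 4.28 ± 0.76 (SE, n = 3 per fusion; adjusted p = 0.000239). The F-box gene fbxc-55 (chromosome II, 3168757 to 3170900) stood at 4.14 ± 0.60. The unconventional myosin gene hum-7 (chromosome I, 585807 to 607571) stood at 4.09 ± 0.69, from 2343 Dam::EMR-1 and 348 GFP::Dam reads. The chemoreceptor genes srbc-2 (4.08 ± 1.27), srv-15 (4.04 ± 1.03) and sru-11 (4.00 ± 1.22) were also among the 12, with gtnt-53 (4.27 ± 0.83), smg-9 (4.23 ± 0.77), sprr-3 (4.13 ± 0.99), tsct-2 (4.13 ± 1.009) and mgl-3 (3.99 ± 1.15), a metabotropic glutamate receptor. The call of sru-11 ended without Dam::EMR-1 wild type replicate 1 (2.64, adjusted p = 0.0765). Thn-5 had the largest fitted ratio (4.66 ± 1.68, adjusted p = 0.0252) from only 25 Dam::EMR-1 and 2 GFP::Dam reads. Its call ended without Dam::EMR-1 replicate 1 (1.82, adjusted p = 0.446) and without each of the 3 GFP::Dam replicates.

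Of the 12 genes with the lowest ratios, 10 lay in centres. The bin of the transporter gene mfsd-12 (chromosome X, 4668088 to 4673234) had 0 Dam::EMR-1 reads over the group against 767 GFP::Dam reads, at least 86.6-fold lower with a floor of 3 reads over the group. On the same floor gana-1 (chromosome V, 12087234 to 12088931), an alpha-galactosidase gene, was at least 37.5-fold lower, and zip-5 (chromosome V, 13264545 to 13269827) at least 29.2-fold lower. The UDP-glucuronosyltransferase gene ugt-18, rer-1 and irld-47 also had 0 Dam::EMR-1 reads, against 314, 180 and 175 GFP::Dam reads. The call of irld-47 (adjusted p = 0.0308) ended without each of the 3 Dam::EMR-1 replicates and without GFP::Dam replicate 2. The sodium and calcium exchanger gene ncx-5 (chromosome V, 10486361 to 10490098) had 7 against 3637 reads and a log2 of −7.46 ± 1.75. The magnesium channel gene gtl-2 (chromosome IV, 11273451 to 11281992) had 10 against 3893 reads, at −7.12 ± 1.43, and the receptor tyrosine phosphatase gene dep-1 (chromosome II, 9005796 to 9019798) had 5 against 2217 reads, at −7.30 ± 1.26. For cpt-6, tres-1 and ugt-17 a single Dam::EMR-1 read stood against 1290, 761 and 425 GFP::Dam reads.

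Over all 9960 tested bins, edgeR called 2527 higher and 2884 lower at an adjusted p under 0.05, and DESeq2 called 2670 higher and 3359 lower. With the replicate number as a block 3205 were higher and 3251 lower. Scaling by library size in place of TMM raised the median wild-type ratio by 0.15.

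Among lists of genes fixed before the data were examined, the intestine list lay mostly in bins low in Dam::EMR-1. No expression was measured, so activity of its genes in these cells was not tested. Of 30 bins of the intestine list, 21 were lower and 2 higher, with a median log2 of −3.65 (camera adjusted p = 0.000141; adjusted p = 0.159 with an estimated correlation). The protease gene asp-1 (chromosome V, 19049562 to 19050752) stood at −6.21 ± 1.19, the sodium and proton exchanger gene nhx-2 at −5.39 ± 1.06, the intermediate filament gene ifb-2 at −5.44 ± 0.95, and elt-2, the GATA factor of intestine identity (chromosome X, 10481240 to 10483441), at −4.16 ± 0.92 (SE, adjusted p = 0.00111, edgeR). Exceptions were elt-7, a second GATA factor of the intestine (1.49 ± 0.50), and the gut esterase gene ges-1 (1.22 ± 0.38), both higher. The yolk protein gene vit-2 was lower (−3.71 ± 1.16), whereas the bins of vit-1, vit-3, vit-4, vit-5 and vit-6 were not called. Of 107 ribosome and proteasome bins 75 were lower and 1 higher, with a median of −2.66 (camera adjusted p = 9.51e-10; adjusted p = 0.159 with an estimated correlation). They included rps-14 (−6.91 ± 1.37) and rpl-3 (−6.16 ± 1.07), while rps-7 was higher (1.09 ± 0.46, adjusted p = 0.0498).

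The lists of chemoreceptors, of F-box, MATH and BTB genes and of C-type lectins shifted up in Dam::EMR-1. Of 791 chemoreceptor bins 355 were higher and 110 lower, with a median of 1.51 (camera adjusted p = 2.81e-07). Of 261 F-box, MATH and BTB bins 97 were higher and 31 lower, with a median of 0.94 (camera adjusted p = 9.91e-05). Of 172 C-type lectin bins 61 were higher and 27 lower, with a median of 0.71 (camera adjusted p = 0.00781). Each of the 3 had an adjusted p of 0.159 with an estimated correlation. Members lay on both sides, such as fbxb-117 (3.49 ± 0.61) and btb-2 (−5.77), clec-193 (3.35 ± 0.83) and clec-178 (−6.07), and srx-76 (−6.18 ± 1.27) beside srz-23.

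Hypodermis genes were lower in 14 of 25 bins and higher in 3 (median −1.69, camera adjusted p = 0.0424). They included the zinc-finger gene lin-26 (−4.39) and the collagen gene rol-6 (−4.15), with mlt-11 (2.56) higher. Histone genes were lower in 9 of 21 bins and higher in 3 (median −1.59, camera adjusted p = 0.0361). Both lists had an adjusted p of 0.267 with an estimated correlation. Muscle (10 of 29 bins lower, 3 higher), neuron (10 of 31 lower, 8 higher), germline (13 of 31 lower, 5 higher), nuclear hormone receptor (61 of 200 lower, 49 higher), collagen (43 of 130 lower, 26 higher) and major sperm protein lists (10 of 24 lower, 5 higher) were not called. Adjusted over the list alone, chemoreceptors had 358 higher and 111 lower, F-box, MATH and BTB genes 96 and 29, and histones 3 and 10, and the other 10 lists had the counts given. Relative to the bins of the same chromosome part, a comparison chosen after seeing the data, 3 lists were called. Intestine stood 1.66 below its part (camera adjusted p = 0.0003), ribosome and proteasome 2.07 below (adjusted p = 9.94e-14) and chemoreceptors 0.75 above (adjusted p = 0.0003). No value with an estimated correlation is at hand for this comparison. Against all bins, each of these 3 lists had a camera adjusted p of 0.159 with an estimated correlation. The F-box, MATH and BTB list, with 93.9% of its bins in arms, lost its call and its median turned to −0.07 (adjusted p = 0.652), and C-type lectins, with 82.1% in arms, turned to −0.09 (adjusted p = 0.684). Hypodermis and histones also lost their call. By fry, muscle (adjusted p = 0.0168), neuron (0.00807), germline (0.00451), collagen (0.0346) and major sperm protein lists (0.000409) were lower too. Nuclear hormone receptors did not pass fry (adjusted p = 0.313).

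**Figure D2:**
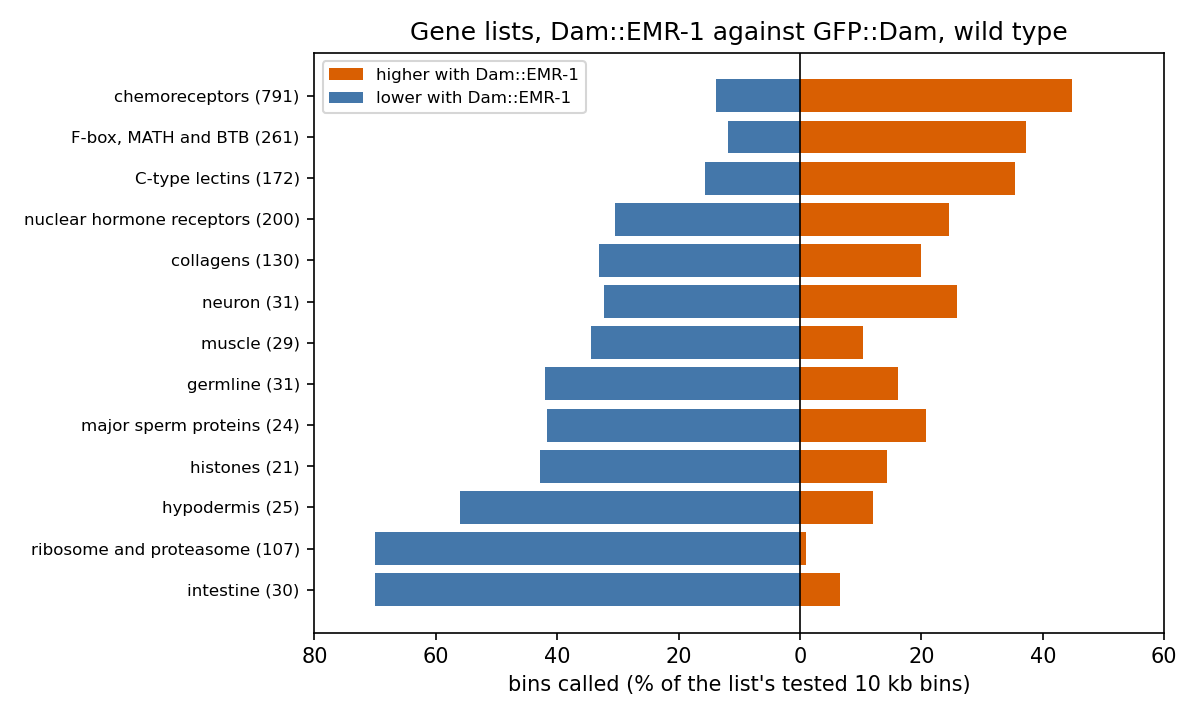
Percent of the 10 kb bins of each of 13 gene lists (horizontal axis) that were higher or lower in Dam::EMR-1 than in GFP::Dam in wild type (edgeR, adjusted p under 0.05, n = 3 per fusion). Intestine has 21 of 30 bins lower and chemoreceptors 355 of 791 bins higher.

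The comparison of cec-4 with wild type asks how far the arms depend on this anchor. The mean ratio of arms minus centres on autosomes was 2.87 ± 0.33 (SD, n = 3 pairs) in wild type and 1.53 ± 0.18 (SD, n = 3) in cec-4. On X the same difference was 1.499 ± 0.161 (SD, n = 3) in wild type and 0.81 ± 0.06 (SD, n = 3) in cec-4. The groups did not overlap on either measure, and all 3 within-number differences were negative, from −1.796 to −1.005 on autosomes and from −0.92 to −0.52 on X. Each of the 5 autosomes had a smaller difference in cec-4, from 2.27 to 0.76 on I, 4.06 to 2.69 on II, 2.71 to 1.22 on III, 2.44 to 1.49 on IV and 2.87 to 1.48 on V. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 allows (Benjamini-Hochberg 0.167 over 5 pairwise comparisons). Permuting genotypes within each RNAi condition, a test added after seeing the data, gave a cec-4 effect of −1.12 on autosomes and −0.56 on X, each with p = 0.005, the smallest that 200 permutations give. When genotypes were swapped only within a replicate number, also added later, all 5 differences were lower on both measures, and the exact p of 0.0625 was the smallest that 32 swaps give.

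**Figure D3:**
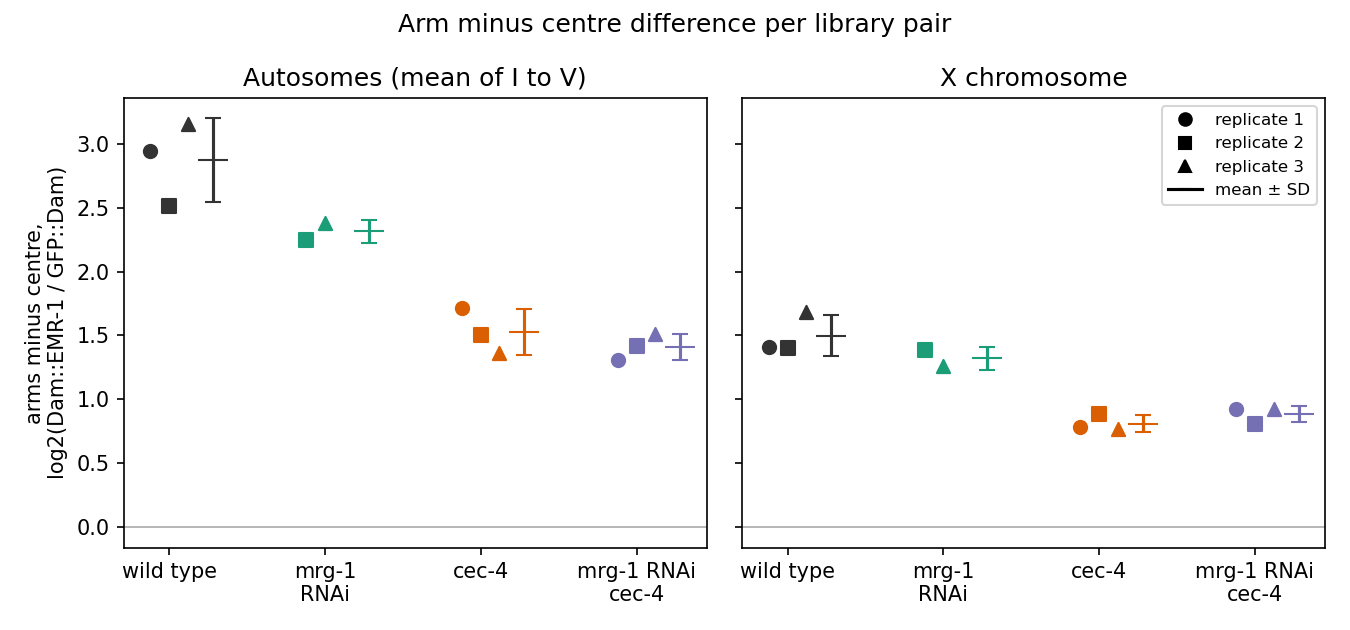
Mean log2 ratio of arms minus centres (vertical axis) for autosomes and X in the 4 backgrounds (horizontal axis), one point per replicate pair, with the group mean and SD. On autosomes the wild-type pairs lie between 2.51 and 3.16, and the cec-4 mean is 1.53.

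By chromosome part, on the scale of read shares, the centres of all 6 chromosomes stood higher in cec-4 and no arm passed the test. The centre of II rose by 1.36 ± 0.25 (SE, adjusted p = 9.92e-06, limma), that of III (4590001 to 9190000) by 1.29 ± 0.25, V by 1.31 ± 0.25, X (5910001 to 11810000) by 1.21 ± 0.25, I by 1.14 ± 0.25 and IV by 0.86 ± 0.25 (adjusted p = 0.00823). Centred on each pair's genome mean, an alternative chosen after seeing the data, 15 parts were called, the 6 centres higher and 9 arms lower. The level of each pair's ratios is set by the scaling, so these fits do not tell a gain in centres from a loss in arms.

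In 100 kb bins, 46 rose and 11 fell in cec-4 among 1004 tested. Of those that rose 30 lay in autosome centres, 3 in autosome arms and 13 on X, and all 11 that fell lay in autosome arms. Examples were chosen after their values were seen. The window from 7100001 to 7200000 on III, which holds ogt-1, the O-GlcNAc transferase gene, rose by 2.16 ± 0.52 (SE, adjusted p = 0.0251), and the window of egl-9, the prolyl hydroxylase gene that controls HIF-1 (chromosome V, from 10400001), rose by 1.91 ± 0.37. The window of the cadherin gene cdh-1 (chromosome III, 2900001 to 3000000), at 2.17 ± 0.21 in wild type, fell by 1.72 ± 0.28 (SE, adjusted p = 0.00428), and that of sms-3 (chromosome III, 1500001 to 1600000) fell by 2.64 ± 0.65. With the replicate number as a block 192 rose and 61 fell. The call rests on scaling and on single libraries, since library size alone gave 0, and 1 was called without GFP::Dam wild type replicate 1 or without GFP::Dam cec-4 replicate 1 or 3, and 4 without GFP::Dam wild type replicate 3. The count was 22 without Dam::EMR-1 wild type replicate 1 or 3, 27 and 36 without Dam::EMR-1 cec-4 replicates 3 and 2, 131 without Dam::EMR-1 wild type replicate 2 and 144 without GFP::Dam cec-4 replicate 2.

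At 10 kb edgeR called 0 bins in cec-4 against wild type, with 551 under an unadjusted p of 0.05, and DESeq2 called 4 higher and 5 lower. Without Dam::EMR-1 wild type replicate 2 edgeR called 12. On simulated data the same 10 kb test found 0 of 50 bins changed by log2 2, and 32 of 50 changed by log2 5, so changes of log2 2 or less in single bins were not detectable with these libraries. At 100 kb it found 48 of 50 at log2 2.

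The comparison of mrg-1 RNAi with wild type asks whether MRG-1 acts on the same anchoring. The arm minus centre difference on autosomes was 2.31 ± 0.09 (SD, n = 2 pairs), against 2.87 ± 0.33 (SD, n = 3) in wild type, with an exact two-sided permutation p of 0.2. On X it was 1.32 ± 0.09 (SD, n = 2) against 1.499 ± 0.161 (exact permutation p = 0.4). The smallest p this design allows is 0.1. Within-number differences ran from −0.78 to −0.26 on autosomes and from −0.43 to −0.01 on X. The groups did not overlap on either measure. Among single autosomes they did not overlap on I (1.55 against 2.27 in wild type, exact permutation p = 0.1), III (1.97 against 2.71, p = 0.2) and IV (2.06 against 2.44, p = 0.2), and they overlapped on II and V. Permutation of the RNAi labels within genotype, added after seeing the data, gave −0.34 on autosomes (p = 0.075) and −0.05 on X (p = 0.64), and −0.45 on autosomes in the Dam::EMR-1 libraries alone (p = 0.035). Swaps within replicate numbers gave exact p values of 0.188, 0.812 and 0.0625 for these, where 0.0625 is the smallest possible. The mean ratio of X minus autosomes was lower after the knockdown in both genotypes, a measure taken up after seeing the data. It was −1.23 ± 0.13 (SD, n = 3) in wild type and −1.63 ± 0.20 (SD, n = 2) with mrg-1 RNAi, and −0.78 ± 0.01 (SD, n = 3) in cec-4 and −1.28 ± 0.33 (SD, n = 3) in the combination. On this measure the same permutation gave −0.45 (p = 0.005, the smallest that 200 permutations give). Differences within replicate numbers ran from −0.53 to −0.38 in wild type and from −0.81 to −0.17 in cec-4, all 5 lower, and swaps within numbers gave an exact permutation p of 0.0625, the smallest possible. The effects in the genotypes differed by −0.11 (interaction, permutation p = 0.78). Permutation of genotypes within RNAi condition gave a cec-4 effect of 0.40 on the same measure (p = 0.02), with all 5 within-number differences higher, from 0.33 to 0.58 (exact permutation p = 0.0625 with swaps within numbers).

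No chromosome part passed the test for mrg-1 RNAi against wild type in limma, with 3 under an unadjusted p of 0.05. The centre of I stood at 0.63 ± 0.28 (adjusted p = 0.104), the centre of III at 0.61 ± 0.28 (adjusted p = 0.115) and the right arm of X at −0.63 ± 0.28 (adjusted p = 0.104). Centred on the genome mean, 4 parts were called, with the centres of I (0.71), II (0.49) and III (0.68) higher and the right arm of X lower (−0.56). Uncentred, 2 parts were called without the wild type pair of replicate 1 and 3 without that of replicate 2. In edgeR 0 bins of 10 kb were called (188 under an unadjusted p of 0.05, 0 in DESeq2) and 0 of 100 kb (53 under an unadjusted p of 0.05). At 10 kb 12 were called without Dam::EMR-1 mrg-1 RNAi replicate 2, and at 100 kb 9 without Dam::EMR-1 wild type replicate 2.

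The combination asks whether the knockdown adds to the loss of CEC-4. On autosomes the arm minus centre difference was 1.41 ± 0.10 (SD, n = 3) and on X 0.88 ± 0.07 (SD, n = 3). Against wild type these were lower by 1.46 and 0.61 (exact permutation p = 0.1 for each), with within-number differences from −1.64 to −1.0957 and from −0.76 to −0.49. Against cec-4 alone the autosomes differed by −0.12 (exact permutation p = 0.5), with within-number differences from −0.41 to 0.15. Each fusion alone was lower in 3 of 3 replicate numbers, Dam::EMR-1 with a mean difference of −0.51 (−0.95 to −0.17, exact permutation p = 0.3) and GFP::Dam with −0.39 (−0.55 to −0.08, exact permutation p = 0.3). Chromosome III showed the clearest step among autosomes, from 1.22 in cec-4 to 0.86, lower in 3 of 3 replicate numbers, with differences from −0.71 to −0.18 (exact permutation p = 0.1). Against mrg-1 RNAi alone the autosomes were lower by 0.90 (exact permutation p = 0.1, within-number −0.87 to −0.83).

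Compared with wild type, the centres of 5 chromosomes rose in the combination, by 1.41 ± 0.25 (SE) on I, 1.18 ± 0.25 on II, 1.46 ± 0.25 on III, 0.69 ± 0.25 on IV (adjusted p = 0.0401, limma, and 0.0647 with the replicate block) and 1.005 ± 0.252 on V. The left arm of III (1 to 4590000) fell by 0.71 ± 0.25 (adjusted p = 0.0347), and the centre of X stood at 0.53 ± 0.25 (adjusted p = 0.115). Compared with cec-4 alone, the centre of X fell by 0.68 ± 0.25 (adjusted p = 0.0419). With the replicate number as a block its adjusted p was 0.0603. In fits without the pair of cec-4 replicate 1 or 3 or combination replicate 1 or 3, 0 parts were called. Centred on the genome mean, with or without the block, 5 parts were called against cec-4. Of these 2 centres were higher, and 1 centre and 2 arms lower. Compared with mrg-1 RNAi alone, the centres of I (0.78), II (0.76), III (0.85), V (0.95) and X (0.80) rose. Only that of III passed with the block, and 0 were called without the pair of mrg-1 RNAi replicate 2 or 3 or combination replicate 1. The limma test of non-additivity of both perturbations called 0 parts, with 0 under an unadjusted p of 0.05. As for cec-4, changes of single parts depend on the scaling of each pair, so gains in centres and losses in arms are not told apart. The spread was again pooled over the parts, so the limma p-values can be too small here too.

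**Figure D4:**
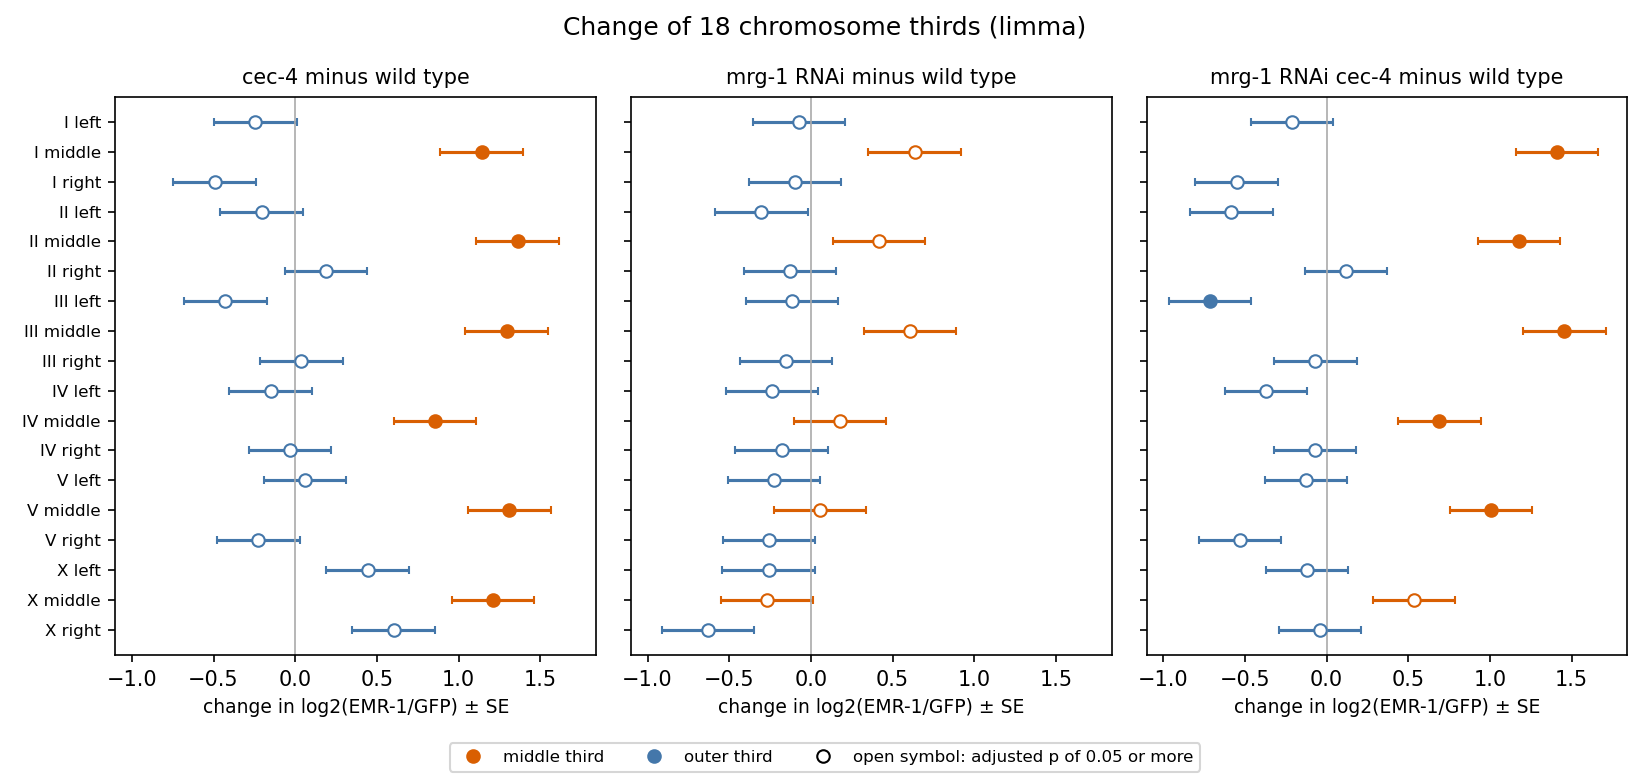
Change of the mean log2 ratio ± SE (horizontal axis) in the 18 chromosome parts (vertical axis) for cec-4, mrg-1 RNAi and the combination, each against wild type. Orange marks centres, blue marks arms, and filled symbols have an adjusted p under 0.05 (limma). In cec-4 the 6 centres lie between 0.86 and 1.36.

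In 100 kb bins, 125 rose and 50 fell in the combination against wild type, and 102 of the 125 lay in autosome centres and 48 of the 50 in autosome arms. The windows named here were chosen after their values were seen. The window of the cadherin gene cdh-4 (chromosome III, from 4500001) rose by 2.14 ± 0.32 (SE, adjusted p = 0.000429), and that of nmtn-1 (chromosome I, from 6400001) by 2.17 ± 0.35. The cdh-1 window fell by 2.21 ± 0.28 (SE, adjusted p = 0.000105), and that of daf-2, the insulin receptor gene (chromosome III, from 3000001), by 2.00 ± 0.42 (adjusted p = 0.00704). The count of 175 was 280 with the replicate block and 55 with scaling by library size alone. It was 97 and 107 without GFP::Dam wild type replicates 1 and 3, 107 without Dam::EMR-1 wild type replicate 1, 70 rising and 34 falling without replicate 3 of that group, and 101 and 113 without GFP::Dam combination replicates 1 and 2. Between the combination and mrg-1 RNAi alone 2 windows fell, frm-8 (chromosome III, 3200001 to 3300000) by 2.51 ± 0.48 and cdh-1 by 1.65 ± 0.32, both with an adjusted p of 0.0166. Single left-out libraries took that count to between 0 and 8.

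At 10 kb edgeR called 0 bins in the combination against wild type (732 under an unadjusted p of 0.05, 32 in DESeq2), 0 against cec-4 (80 and 0), 0 against mrg-1 RNAi (304 and 0) and 0 for non-additivity (95 and 0). Without Dam::EMR-1 wild type replicate 2 it called 34 in the combination against wild type, and without Dam::EMR-1 mrg-1 RNAi replicate 2 it called 16 against mrg-1 RNAi and 1 for non-additivity. At 100 kb it called 0 against cec-4 (39 under an unadjusted p of 0.05) and 0 for non-additivity (11). Across all 10 kb bins, the change with mrg-1 RNAi in wild type and that in cec-4 had r = 0.06, and the change with cec-4 without and with RNAi had r = 0.39. Bins are not independent replicates, and these r values were 0.39 and 0.74 in 100 kb bins.

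No list of genes held a called bin in any background against wild type, and in the combination 1 hypodermis bin was higher when adjusted over the list alone. As sets, camera called 6 lists in cec-4. F-box, MATH and BTB genes shifted down (median −0.35, adjusted p = 5.43e-06) with C-type lectins (−0.09), and muscle (0.70), hypodermis (0.96), germline (0.58) and major sperm protein genes (0.77) shifted up. With an estimated correlation none was called (adjusted p from 0.171 to 0.399). Relative to the same chromosome part only muscle and major sperm protein genes were called, and F-box, MATH and BTB genes stood at −0.14 (adjusted p = 0.348) and C-type lectins at 0.06 (adjusted p = 0.868). Under mrg-1 RNAi alone ribosome and proteasome genes (0.49, adjusted p = 0.000468) and germline genes (0.33) shifted up and F-box, MATH and BTB genes down (−0.26), none with an estimated correlation (adjusted p = 0.790) or relative to the same chromosome part. In the combination 8 lists were called, with F-box, MATH and BTB genes down (−0.68, adjusted p = 8.05e-13), C-type lectins down (−0.16) and muscle (0.57), hypodermis (0.89), germline (0.87), ribosome and proteasome (0.70), collagen (0.66) and major sperm protein genes (0.89) up. Of these 8, only the F-box, MATH and BTB list held with an estimated correlation (adjusted p = 0.0297), and its median relative to the same chromosome part was −0.39 (adjusted p = 0.00184). Hypodermis and C-type lectins lost their call in that comparison. By fry, neuron and major sperm protein genes were higher in cec-4 (adjusted p = 0.0311 for each), and no list passed under mrg-1 RNAi (0.985). In the combination fry had neuron, germline and major sperm protein genes higher and F-box, MATH and BTB genes lower (0.0223 for each). Hypodermis and collagen genes were higher there too (0.0432 for each). Median, mean and direction differed in sign in cec-4 for chemoreceptors (−0.04, 0.10, down), histones (−0.03, 0.25, up) and nuclear hormone receptors (0.17, 0.28, down), none of them called. The same held in the combination for chemoreceptors (−0.05, 0.08, down) and nuclear hormone receptors (−0.14, 0.00284, down). With mrg-1 RNAi it held for hypodermis (−0.11, 0.35, up), major sperm protein (−0.18, 0.06, up), neuron (−0.07, 0.11, up), collagen (−0.01, 0.07, up), C-type lectin (−0.01, 0.02, down) and muscle lists (0.02, 0.01, down), and none of these was called.

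The GFP::Dam libraries alone ask whether accessibility differed between backgrounds. In edgeR 0 bins of 10 kb were called in cec-4, mrg-1 RNAi or the combination against wild type, with 59, 6 and 2 under an unadjusted p of 0.05, and 0 in DESeq2. The arm minus centre difference of GFP::Dam alone on autosomes was −0.36 ± 0.14 (SD, n = 3) in wild type and 0.16 ± 0.43 (SD, n = 3) in cec-4 (exact permutation p = 0.2), with within-number differences from −0.09 to 0.84. That of Dam::EMR-1 alone was 2.51 ± 0.20 (SD, n = 3) in wild type, 1.68 ± 0.52 (SD, n = 3) in cec-4 and 1.18 ± 0.14 (SD, n = 3) in the combination, with within-number differences to wild type from −1.09 to −0.39 in cec-4 and from −1.397 to −1.258 in the combination. The bin of the ribosomal RNA repeat (chromosome I, 15060001 to 15070000), with rrn-1.1, rrn-2.1 and rrn-3.1, took 17.4% ± 8.67 (SD, n = 11) of GFP::Dam reads and 0.981% ± 0.377 (SD, n = 11) of Dam::EMR-1 reads. In the wild-type test its log2 was −4.12 ± 1.78 (SE, adjusted p = 0.0559, edgeR).

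**Figure D5:**
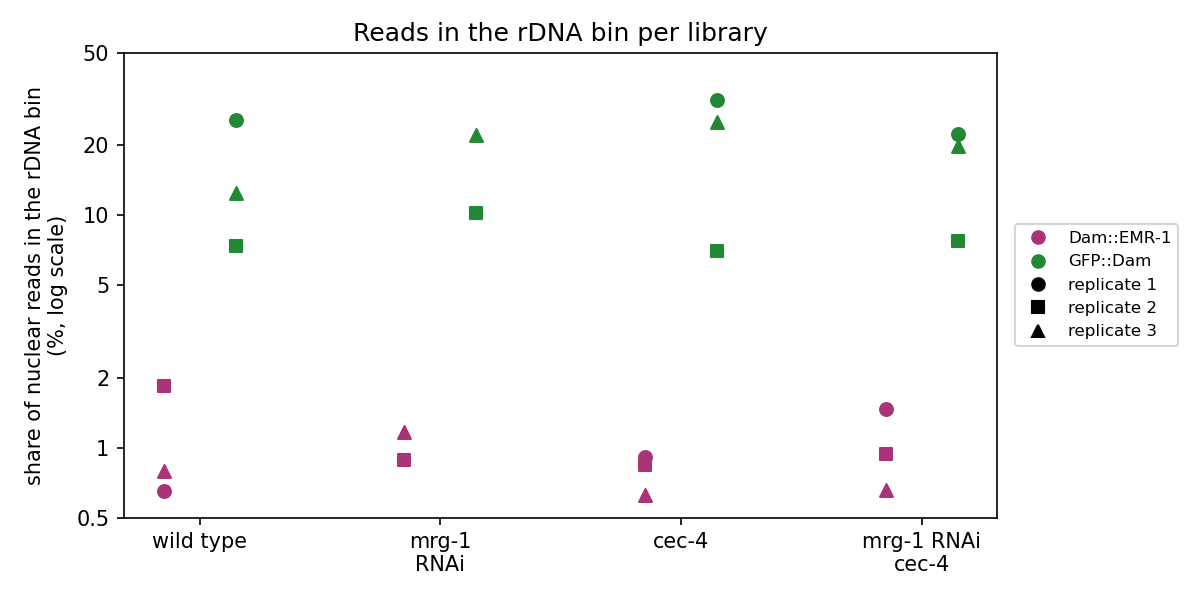
Percent of reads in the 10 kb bin of the ribosomal RNA repeat (vertical axis, log scale) in each library, by fusion and background (horizontal axis). GFP::Dam libraries lie between 7.06% and 31.3%, and Dam::EMR-1 libraries between 0.626% and 1.84%.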

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

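The tests of the GFP::Dam and Dam::EMR-1 libraries alone, of X minus autosomes and of the ribosomal RNA bin were chosen only after the results they bear on were seen, as were the thinning of libraries, swaps within replicate numbers and the 100 kb counts with the replicate block, and the other tests here were planned.

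The smaller arm minus centre difference in cec-4 and in the combination was weighed against 3 technical explanations. A general damping of the ratio would shrink local contrast too. The bin-to-bin amplitude within 100 kb windows that replicates share was 0.971 of wild type in cec-4 (0.817 to 1.09 with each replicate pair left out). In the combination it was 1.04, whereas the regional differences fell to 0.532 in cec-4 and 0.492 in the combination. This amplitude is that of the ratio and holds the local pattern of GFP::Dam too. It therefore cannot tell whether the Dam::EMR-1 signal alone was damped. With every library thinned to the shallowest, 2240350 reads, the autosome differences to wild type were −1.34 and −1.47, which argues against depth. In the Dam::EMR-1 libraries alone they were −0.82 and −1.33, so a change in the control alone would not account for them, although GFP::Dam alone in cec-4 stood 0.52 above wild type (exact permutation p = 0.2) and may add to the cec-4 value. An effect of the cec-4 deletion stays open as a hypothesis, and so do other differences between the strains, since genotype and transgenic strain coincide, and no test here bears on a mechanism.

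The lower ratio of X minus autosomes under mrg-1 RNAi appears within the same strains with and without RNAi. RNAi minus control was −0.46 in the Dam::EMR-1 libraries alone and −0.01 in the GFP::Dam libraries alone (permutation p = 0.805), with within-number differences from −0.72 to −0.12 and from −0.03 to 0.09, which argues against a change in the control as the cause. With every library thinned to the shallowest it was −0.45, which argues against depth. A biological effect of the knockdown stays open as a hypothesis, and no mechanism was tested; this measure was noticed in the same data and rests on 2 pairs of mrg-1 RNAi and 3 of each other background, and swaps within replicate numbers gave an exact permutation p of 0.0625, the smallest they allow.

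The bin of the ribosomal RNA repeat held a larger share of GFP::Dam than of Dam::EMR-1 reads in each of the 4 backgrounds. Collapse of repeat copies onto a single bin would raise both fusions alike, but the lowest GFP::Dam share was 3.83 times the highest Dam::EMR-1 share. Within GFP::Dam the share went with the replicate number, at 7.06% to 10.2% in the 4 libraries of replicate 2 and 12.504% to 31.3% in the other 7. No biological explanation of the difference between fusions was tested, and how repeated reads were mapped is not stated.

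Mitochondrial DNA, which no comparison used, gave more reads in a pair of Dam::EMR-1 libraries than in any GFP::Dam library. Wild type replicate 1 had 118 mitochondrial reads per 1e+06 reads (296 reads) and combination replicate 1 had 69.4 (232 reads), while 14 of the 22 libraries had 0. Among GFP::Dam libraries wild type replicate 2 had the most, at 13.9 (70 reads), and wild type replicate 1 had 25 reads and mrg-1 RNAi replicate 2 had 16.

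Groups of 3 against 3 give 10 splits, too few for a share under 0.05, so only the real value and the highest of the other splits are given here. For wild type the 10 kb counts were 5411 and 0, and 1 of the 10 splits reached the real count. For 100 kb bins they were 57 and 0 in cec-4 and 175 and 0 in the combination, and with the replicate block 253 and 0, and 280 and 2, with 1 split as large in each case. For chromosome parts they were 6 and 0 in cec-4, 6 and 0 in the combination, and 1 and 0 for the combination against cec-4. For called gene lists they were 7 and 7 in wild type (3 splits as large), 6 and 7 in cec-4 (3 splits) and 8 and 9 in the combination (2 splits). For 10 kb bins with a real count of 0, all 10 splits are as large, and the highest other was 7 in cec-4, 1 in the combination and 0 for the combination against cec-4 and for GFP::Dam alone in cec-4 and the combination. Besides the real split, 3 of the others part every replicate number, and their highest counts were 7, 7 and 9 for the lists in wild type, cec-4 and the combination and 0 for the bins of 10 and 100 kb and for chromosome parts.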

How the results depend on the processing

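Settings marked with "added" were chosen only after seeing the data, and the others were planned. Of 908 alternatives to 71 results, 758 kept their direction and their side of the threshold or stayed near the first value, 133 moved, 15 were weaker, 1 stronger and 1 reversed; for those that changed, the cause was not tested. The called bins of wild type stayed within 4489 and 6456 at 10 kb over the settings with that bin size. The smaller arm minus centre difference in cec-4 and in the combination kept its direction in all settings, from 1 kb to 100 kb bins. Of 29 named genes, called or not, 28 kept their side of the threshold with scaling by library size (emr-1 did not, at −0.93) and 29 with DESeq2, with no filter and with the replicate block, and 158 of 174 values with a library left out kept theirs. In the simulated data few 10 kb bins were recovered below a change of log2 5; depth and the spread between replicates were not separated as limits.

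In 1 kb bins the called bins numbered 18176 in wild type, 1 in cec-4 and 1 in the combination. The arm minus centre difference on autosomes was 1.43 in wild type, with changes of −0.75 in cec-4, −0.28 with mrg-1 RNAi and −0.74 in the combination against wild type, −0.46 for the combination against mrg-1 RNAi, and 0.0111 for the combination against cec-4, which reversed. On X it was 0.68 in wild type, with −0.33 in cec-4, −0.30 in the combination and −0.16 for the combination against mrg-1 RNAi. Called parts were 2 in the combination, 0 against cec-4 and 0 against mrg-1 RNAi.

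In 100 kb bins the called bins numbered 772 in wild type, 57 in cec-4, 175 in the combination and 2 for the combination against mrg-1 RNAi. The autosome difference for the combination against mrg-1 RNAi was −0.79, and on X the wild-type value was 1.70, the combination against cec-4 0.00529 and against mrg-1 RNAi −0.53. Called parts were 10 in cec-4, 4 with mrg-1 RNAi and 3 for the combination against cec-4, and r between changes was 0.39 for mrg-1 RNAi in both genotypes and 0.74 for cec-4 in both RNAi conditions. With the replicate block (added) the 100 kb counts were 826, 253, 280 and 10 in the same order, with scaling by library size (added) 757 in wild type and 55 in the combination, and with a block for each fusion (added) 807, 358, 347 and 121, with 2 for mrg-1 RNAi. At 10 kb DESeq2 called 9 in cec-4 and 32 in the combination.

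With a pseudocount of 5 the autosome difference was 2.33 in wild type, with −1.07 in cec-4, −1.14 in the combination and −0.675 for the combination against mrg-1 RNAi. On X it was 1.19, with −0.53, −0.49 and −0.28 in the same order, and called parts were 0 for the combination against cec-4 and 3 against mrg-1 RNAi. With counts summed over each part the autosome value was 2.42 in wild type and −0.75 for the combination against mrg-1 RNAi, X was 1.71, and 3 parts were called with mrg-1 RNAi and 3 for the combination against cec-4. With narrower arms, the outer parts of chromosomes divided into 4, X was 1.75 in wild type, and 2 parts were called for the combination against cec-4 and 3 against mrg-1 RNAi. At recombination-rate boundaries X was 1.24 and 2 parts were called for the combination against cec-4. The deposited log2 table gave −1.05 on autosomes and −0.52 on X for the combination against mrg-1 RNAi. With the replicate block 0 parts were called for the combination against cec-4 and 1 against mrg-1 RNAi. Centred on the genome mean (added), called parts were 15 in cec-4, 4 with mrg-1 RNAi and 13 in the combination, with 5 against cec-4 and 12 against mrg-1 RNAi, and with the block as well (added) 15, 4, 12, 5 and 12. Without the ribosomal RNA bin (added) 1 part was called with mrg-1 RNAi.

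With an estimated correlation the called lists numbered 0 in wild type, cec-4 and mrg-1 RNAi and 1 in the combination. Relative to the same chromosome part (added) they were 3 in wild type, 2 in cec-4, 0 with mrg-1 RNAi and 6 in the combination.

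With single libraries left out, 10 kb bins called ran from 0 to 12 in cec-4 and from 0 to 34 in the combination, both highest without Dam::EMR-1 wild type replicate 2. They ran from 0 to 12 with mrg-1 RNAi, from 0 to 16 for the combination against mrg-1 RNAi and from 0 to 1 for non-additivity, all highest without Dam::EMR-1 mrg-1 RNAi replicate 2. With single pairs left out, called parts ran from 0 to 3 with mrg-1 RNAi (2 without wild type replicate 1 and 3 without replicate 2), from 0 to 1 for the combination against cec-4 (0 without cec-4 or combination replicate 1 or 3) and from 0 to 4 for the combination against mrg-1 RNAi (0 without mrg-1 RNAi replicate 2 or 3 or combination replicate 1, and 3 without combination replicate 2). A group left with 1 library is assumed to vary like the others.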

Other observations

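The values per gene in the next paragraph follow lists fixed before the data were examined. Apart from the planned edgeR test at mrg-1, the other examples and tests here were chosen only after the results were seen.

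Several lists, most of them not called as sets, held genes at both extremes in wild type. Among muscle genes, hlh-1, the MyoD homologue, was higher in Dam::EMR-1 (2.21 ± 0.51, SE) and the cofilin gene unc-60 lower (−4.94 ± 1.03). Among neuron genes, unc-17, the vesicular acetylcholine transporter gene, was higher (2.05 ± 0.85) and the synaptotagmin gene snt-1 lower (−6.16 ± 1.26). In the germline list mex-3, an RNA-binding regulator of early embryos, was higher (3.14 ± 0.64) and puf-5 lower (−5.21 ± 0.88). Among nuclear hormone receptors nhr-244, in the same bin as gtnt-53, stood at 4.27 ± 0.83. The lowest bin of that list, which holds nhr-206 and has 4 genes of the list, had a fitted value of −9.27 ± 2.92. The bins of gana-1 and zip-5, with fitted values of −9.52 and −9.36, had 0 Dam::EMR-1 reads, so this value may also lie at the floor. The bin of nhr-232 stood at −6.03 ± 0.84. Among collagens col-163 stood at 3.04 ± 0.42 and col-78 at −5.72 ± 1.19. Histone bins ran from his-40 (−5.86 ± 0.83) to his-67 (1.80 ± 0.62), and major sperm protein bins from msp-64 (−3.92 ± 0.997) to msp-51 (3.38 ± 0.86). Histone and major sperm protein genes have near-identical copies.

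The ends of the X chromosome were also measured apart. Its left arm minus its centre was 1.60 ± 0.18 (SD, n = 3) in wild type and 1.60 ± 0.01 (SD, n = 2) with mrg-1 RNAi, and its right arm minus its centre was 1.40 ± 0.20 and 1.04 ± 0.19 in the same groups (exact permutation p = 0.2). Within replicate numbers RNAi minus control ran from −0.16 to 0.00222 on the left and from −0.69 to −0.03 on the right. In cec-4 the left and right values were 0.83 and 0.79, with within-number differences to wild type from −1.002 to −0.61 and from −0.83 to −0.34.

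In 1 kb bins 1 bin was called in cec-4 and the same bin in the combination, on chromosome III from 11470001 to 11471000, overlapping bed-2 (11463665 to 11470808), with adjusted p = 0.000893 and 0.00637 (edgeR). It held 40 to 124 reads per library with Dam::EMR-1 in wild type and 0 to 2 with GFP::Dam. With mrg-1 RNAi it held 37 to 127 and 1 to 3. In cec-4 the order turned, with 0 reads in all 3 Dam::EMR-1 libraries and 123 to 509 with GFP::Dam, and in the combination it was 0 to 4 and 113 to 342. The reads thus went with the 4 strains, with or without RNAi.

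At the mrg-1 gene on chromosome III, a pair of 1 kb bins held more Dam::EMR-1 reads in the libraries of mrg-1 RNAi, mainly in replicate 3. Scaled to 1e+06 reads, the bin from 12872001 to 12873000 stood at 5.57 in replicate 2 and 57.5 in replicate 3 (22 and 290 reads), against 3.26 ± 2.02 (SD, n = 3) in wild type, 2.02 ± 1.31 in cec-4 and 1.59 ± 1.07 in the combination. The bin from 12874001 to 12875000 stood at 20.5 and 129 (81 and 652 reads), against 16.2 ± 2.40 (SD, n = 3) in wild type, 10.2 ± 4.71 in cec-4 and 9.28 ± 5.43 in the combination. With GFP::Dam under mrg-1 RNAi these bins held 2.56 ± 2.66 and 8.61 ± 5.10 (SD, n = 2). The planned edgeR test of RNAi against control, with both fusions and genotypes together, called neither bin (log2 1.11 ± 0.51 and 0.37 ± 0.41, SE). The source of these reads was not tested.

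The share of 1 kb bins without a read went with the replicate number, and in each of the 8 groups replicate 2 had the lowest share. In GFP::Dam it was 19.2% to 20.5% in the 4 libraries of replicate 2, which were also the shallowest of that fusion, and 24.5% to 46.8% in the other 7. Dam::EMR-1 cec-4 replicate 1, with 8202910 reads, had 62.4%, and replicate 2 of that group, with 4359680 reads, had 25.2%.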
